A study of Rattus norvegicus with 8 samples.

How the data were processed

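Total RNA of whole rat hearts was labelled with Cy3 and hybridised to Agilent whole genome arrays, 1 sample per array, at day 6 of an acute doxorubicin cardiomyopathy model. Per the labels, 8 arrays covered 4 groups (Control, Dox, TPO, TPO+Dox). That the 2 samples of each group are biological replicates comes from the series design. No vehicle treatment of the Control rats is named. Per the labels, RNA was extracted with Trizol and RNeasy, and cRNA was made with the Agilent Low RNA Input kit.

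The scanner files hold spot values as intensity; the authors scanned each array and Feature Extraction subtracted background, detrended the signal and put surrogate values near background, without normalization between arrays, per the file headers. The headers give Feature Extraction 9.5.3.1, while the submitters' notes name 9.1. The deposited value table holds log2 values that the authors shifted by a constant per array and centred on the median of the 8 arrays for each probe. The scale, the centring and the direction of that table are not written with it and were read from the values. Over 19548 probes, the table followed log2 processed signal centred on each probe's median, with slopes of 0.92 to 1.00 and r of 0.971 to 0.985. The table stood above that signal by a median of 0.683 for Dox replicate 1, whose 75th percentile was lowest (233). It stood lowest for TPO replicate 1 (-0.321), whose 75th percentile was highest (468). Its column medians were -0.0218 and -0.114 (Control replicates 1 and 2), 0.0642 and -0.0922 (Dox), -0.289 and 0.175 (TPO+Dox), and 0.0594 and 0.146 (TPO). It has 41090 rows, of which 41012 matched a probe.

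Each array had 43379 spots, 1639 of them controls, with 71 to 142 spots marked as outliers and 0 to 2 saturated. The 75th percentile of the processed signal ran from 233 to 468. Probes well above background numbered 21251 (TPO+Dox replicate 2) to 26370 (Dox replicate 2). The lowest signal counted as well above background was 22.2 to 25.8 on the arrays of lot 2 and 9.71 to 14.1 on those of lot 1. Slides and scan days were read from the file headers: the arrays lay on 5 slides, scanned on 4 days. The lot was inferred from the slide barcode less its last digits, which gave 2 lots. All arrays of lot 2 were scanned on the last scan day and those of lot 1 on earlier days. Differences between the lots thus cannot be told apart from scan day. TPO+Dox replicate 1 was from lot 1 and replicate 2 from lot 2.

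Control spots and outlier spots were dropped, spots of a probe were averaged, and 124 probes with an outlier value were left out, leaving 40888. Signals were taken as log2 of the processed signal less the array's 75th percentile. Probes were named from their accession (10735), symbol (5571) or synonym (3729) in the rat gene table, and 20977 kept only the name in the file; the GRCr8 gene table served for names alone. Probe coordinates are on rn3 per the file headers and were not mapped again. The probe with the highest mean over the 8 arrays stood for each of 35437 genes and transcripts. A gene was tested when its probe was well above background on both arrays of at least 1 group, which left 22086.

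A limma model of 4 group means was fitted to all 8 arrays, with moderated variances and 6 comparisons: Dox against Control, TPO+Dox against Dox, TPO against Control, TPO+Dox against TPO, TPO+Dox against Control, and the interaction. P-values were two-sided and adjusted by Benjamini and Hochberg within each comparison, at a threshold of 0.05. A gene was named when it was among the 12 largest rises or 12 largest falls that passed, had a symbol and no overlap between arrays, and was well above background on both arrays of the higher group. Where none passed, the 5 smallest p were named, and up to 6 members were considered per list. Of 42 lists fixed before the data were examined, 40 had at least 5 tested members and were tested with camera at a preset correlation of 0.01, with an estimated correlation, and with fry; B and plasma cells and thymus had 4 tested members each and were not tested. Adjustment over the list alone used only the members of that list.

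The steps were tested on simulated data with 22086 genes, a small part of them changed. For Dox against Control, 0 of 50 genes changed 2-fold were called, 12 of 50 at 4-fold, 38 of 50 at 8-fold and 45 of 50 at 16-fold. Of 99 genes called, 4 were unchanged ones. A cell cycle list shifted by -1 was called lower (camera adjusted p = 5.44e-22) and 0 of 39 other lists were called. Noise was drawn independently for each gene, without slide or lot effects. The simulation therefore cannot show how often lists of correlated genes are falsely called.

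Alternatives were normexp background correction with an offset of 50, quantile normalization, scaling by the median, the authors' value table, no filter, a filter on all 8 arrays, the mean of all probes of a gene, an intensity trend with a robust prior, blocks for replicate, slide, lot and scan day, a fit of only the groups compared, and each array left out in turn. Fits within slide 2, lot 1 and lot 2, and list tests with a lot block or without each array, were added after the results were seen. The correlation between comparisons that share the Dox arrays was simulated 100 times. Software was Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, matplotlib 3.10.9, R 4.3.3, limma 3.58.1 and statmod 1.5.0. Raw spot and local background signals entered only the normexp alternative.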

Results

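Gene expression was measured in whole rat hearts at day 6 on 8 Agilent one-colour arrays, with 2 biological replicates in each of 4 groups: Control, Dox, TPO and TPO+Dox. Doxorubicin (Dox), an anthracycline cancer drug that poisons type II topoisomerases, was given at 17.5 mg/kg on day 0. Thrombopoietin (TPO), the hormone that drives platelet production, was given at 10 µg/kg on days -1, 1, 3 and 5. Between 21251 and 26370 of the 41012 probes stood well above background on each array, and no array had more than 2 saturated spots. The small number of arrays limits the precision of every value. Replicates correlated across genes at r = 0.974 in Control, 0.980 in Dox, 0.988 in TPO and 0.946 in TPO+Dox. The SD of the replicate difference was 1.07 log2 in TPO+Dox and 0.50 to 0.70 in the other groups; genes are not independent replicates. Control and Dox arrays came from slide lot 1 and TPO arrays from lot 2, while TPO+Dox had 1 array from each lot.

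Changes are log2 differences between group means with their standard errors, over 2 arrays per group, from a limma model of 22086 genes and transcripts. An exact two-sided permutation of 2 arrays against 2 cannot give a p under 0.333, so single genes were tested with limma alone. Where a probe was below background on both arrays of the lower group, the fold is a bound: the mean of the higher group against, on each array of the lower group, the lowest signal counted as well above background or the probe's own signal where that was higher. Lists of genes were tested with limma's camera at a preset correlation of 0.01. No list passed in any of the 6 comparisons when that correlation was estimated from the data, so the adjusted p with an estimated correlation is given beside each call.

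Dox against Control addressed what doxorubicin did to the heart 6 days after a single dose. It changed 1062 genes and transcripts, 339 higher and 723 lower, each without overlap between the arrays of the groups. The fitted change was at least 2-fold for each, though for 274 of them the fold is only a bound. Gal, the neuropeptide galanin, rose most, by 6.83 ± 0.98 (114-fold, adjusted p = 0.014; chromosome 1, 206089883 to 206089942 on rn3). Gdf15, a secreted protein induced by p53 and by cell stress, rose by 4.29 ± 0.29 (19.5-fold, adjusted p = 0.0017; chromosome 16, 19313388 to 19313447). The acute phase proteins Serpina3n and Orm1 rose by 4.56 ± 0.70 (adjusted p = 0.016) and 4.19 ± 0.39 (adjusted p = 0.0041). Hamp, the iron hormone hepcidin, rose by 3.86 ± 0.77 (adjusted p = 0.035), and Cyp2e1, a cytochrome P450 that oxidises ethanol, by 4.12 ± 0.40 (adjusted p = 0.0045). Bex1 rose by 3.69 ± 0.42 (adjusted p = 0.0063). The transcription factor Foxq1 was at least 19.6-fold higher (adjusted p = 0.023), Pth at least 4.46-fold (adjusted p = 0.016) and Lyzl1 at least 2.02-fold (adjusted p = 0.0043).

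The largest falls of single genes after Dox included genes of red cells. Alas2, the erythroid enzyme that starts haem synthesis, fell by 8.28 ± 0.54 (310-fold, adjusted p = 0.0017; chromosome X, 39863822 to 39863881). Hbb, a beta-globin, was at least 341-fold lower (adjusted p = 0.012; chromosome 1, 161701424 to 161701483). Hba-a3, an alpha-globin, fell by 9.05 ± 0.61 (adjusted p = 0.0017), though its probe cannot be assigned with certainty to a single alpha-globin gene. The red cell membrane gene Add2 was at least 45.5-fold lower (adjusted p = 0.0017). Of 15 erythroid markers, 8 fell and 7 did not pass (9 fell when adjusted over the list alone), with a list median of -1.90 (camera adjusted p = 3.1e-08, and adjusted p = 0.19 with an estimated correlation).

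Markers of platelets, T and NK cells and mast cells and genes of MHC class II fell as lists, while those of neutrophils and of macrophages gave no call. Of 9 platelet and megakaryocyte markers, 6 fell and 3 did not pass (7 adjusted over the list alone), with a median of -2.07 (adjusted p = 6.0e-08, and adjusted p = 0.15 with an estimated correlation). They included Treml1, a receptor stored in platelet granules, at -5.78 ± 0.57 (well above background on 1 of 2 Dox arrays), and Pf4, a platelet chemokine, at -1.31 ± 0.28. Of 17 T and NK cell markers, 10 fell and 7 did not pass (16 adjusted over the list alone), with a median of -1.89 (adjusted p = 4.4e-12, and adjusted p = 0.19 with an estimated correlation). Among them were Cd3d and Cd3g, chains of the T cell receptor complex, at -1.68 ± 0.28 and -2.61 ± 0.44, and Prf1, the pore protein of killer cells, at -2.32 ± 0.38. Mast cell markers fell for 5 of 10, with 5 not passed (7 adjusted over the list alone) (list median -1.58, adjusted p = 4.2e-05, and adjusted p = 0.19 with an estimated correlation). They included the proteases Mcpt1 at -3.30 ± 0.41 (well above background on 1 of 2 Dox arrays) and Cma1 at -2.95 ± 0.45. Of 9 genes of MHC class II antigen presentation, 2 fell and 7 did not pass (6 adjusted over the list alone) (list median -2.45, adjusted p = 0.00051, and adjusted p = 0.38 with an estimated correlation). Cd74, the invariant chain, stood at -2.45 ± 0.44, and the regulator Ciita passed but was not well above background on either Dox array, so no fold is given. The 10 neutrophil markers had a median of -0.28 and gave no call (adjusted p = 0.11), with S100a8, a calcium-binding protein of neutrophils, at -1.93 ± 0.38 (adjusted p = 0.033). Cd52, a surface protein of lymphocytes, fell by 5.93 ± 0.43 (adjusted p = 0.0023).

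Genes of cell division and of the matrix fell together with these blood cell markers. Of 44 cell cycle genes, 23 fell and 21 did not pass (29 adjusted over the list alone), with a median of -2.05 (adjusted p = 1.2e-17, and adjusted p = 0.19 with an estimated correlation). Top2a, the topoisomerase of dividing cells, was at least 29.2-fold lower (adjusted p = 0.0036), the mitotic cyclin gene Ccnb1 fell by 3.65 ± 0.31 (adjusted p = 0.0036), and Spc25, of the kinetochore, was at least 21.4-fold lower (adjusted p = 0.0036). Pimreg, a mitotic regulator, was at least 37.0-fold lower (adjusted p = 0.0030), Espl1, the protease that separates sister chromatids, at least 11.1-fold (adjusted p = 0.0025), and Krt24, a keratin, at least 47.2-fold (adjusted p = 0.0018). Of 34 matrix and fibrosis genes, 12 fell and 22 did not pass (13 lower and 2 higher adjusted over the list alone), with a median of -1.02 (adjusted p = 4.2e-06, and adjusted p = 0.19 with an estimated correlation). The fibrillar collagens Col3a1, Col1a1 and Col1a2 fell by 4.17 ± 0.27, 3.28 ± 0.42 and 2.75 ± 0.34 (adjusted p = 0.0017, 0.0094 and 0.0081). They are also among the 15 fibroblast markers, of which 8 fell and 7 did not pass (12 adjusted over the list alone; median -1.84, adjusted p = 6.4e-10, and adjusted p = 0.19 with an estimated correlation). Lum, a matrix proteoglycan, stood at -3.26 ± 0.33. The 10 mesothelial and epicardial markers were all lower with none passing (median -0.997, adjusted p = 0.00033, and adjusted p = 0.38 with an estimated correlation).

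Lists that rose began with cardiac stress. Among 17 cardiac stress and fetal genes, 2 rose, 1 fell and 14 did not pass (11 higher and 1 lower adjusted over the list alone), with a median of 1.04 (adjusted p = 4.2e-06, and adjusted p = 0.30 with an estimated correlation). Nppa, the atrial natriuretic peptide, rose by 2.01 ± 0.43 (adjusted p = 0.043) beside Gdf15, and Acta1, skeletal alpha-actin, fell by 1.93 ± 0.38 (adjusted p = 0.034). Among 19 genes induced by glucocorticoids, 5 rose and 14 did not pass (11 adjusted over the list alone; median 1.11, adjusted p = 1.6e-05, and adjusted p = 0.25 with an estimated correlation). Zbtb16, a transcription factor, stood at 4.34 ± 0.81 and Glul, glutamine synthetase, at 2.32 ± 0.51. Among 22 p53 targets, 4 rose, 1 fell and 17 did not pass (7 higher and 1 lower adjusted over the list alone; median 0.55, adjusted p = 0.0014, and adjusted p = 0.19 with an estimated correlation). Cdkn1a, a cell cycle inhibitor that is also in the glucocorticoid list, stood at 1.62 ± 0.34 and Sesn1 at 1.85 ± 0.36. Among 20 sarcomere genes, 2 rose and 18 did not pass (5 adjusted over the list alone; median 0.62, adjusted p = 4.4e-05, and adjusted p = 0.38 with an estimated correlation). Myot, a Z-disc protein, rose by 3.35 ± 0.49 and Myom2, of the M-band, by 2.06 ± 0.41. Among 22 muscle atrophy and autophagy genes, 3 rose, 1 fell and 18 did not pass (4 higher and 1 lower adjusted over the list alone; median 0.66, adjusted p = 0.0017, and adjusted p = 0.19 with an estimated correlation). Fbxo32, the ubiquitin ligase atrogin-1, stood at 2.96 ± 0.52 and Mstn, myostatin, at least 3.26-fold lower. Among 13 circadian clock genes, 2 rose and 11 did not pass (7 adjusted over the list alone; median 1.12, adjusted p = 0.014, and adjusted p = 0.19 with an estimated correlation). Nr1d1 rose by 2.42 ± 0.47 and Per2 by 2.08 ± 0.42. The circadian call ended without Control replicate 1 (adjusted p = 0.065). Fatty acid oxidation fell as a list with none of 32 members passing (median -0.35, adjusted p = 0.043, and adjusted p = 0.74 with an estimated correlation). That call ended without Control replicate 1, Control replicate 2 or Dox replicate 2 (highest adjusted p = 0.37).

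The other 24 lists tested gave no call (adjusted p from 0.064 to 0.98). Fry kept 12 of the 16 list calls and ended those of sarcomere (adjusted p = 0.087), MHC class II (0.085), mesothelium (0.087) and fatty acid oxidation (0.31). No overlap between the arrays of the groups was seen for 57.3% of all genes tested, against 33.3% by chance. Within slide 2, which held 1 Control and both Dox arrays, 508 genes passed, within lot 1 1075, and with lot as a block 2133. The count was 48 without Dox replicate 2, 130 without Control replicate 1 and 133 without Control replicate 2, 2102 with slide as a random block and 3 with normexp background correction.

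**Figure D1:**
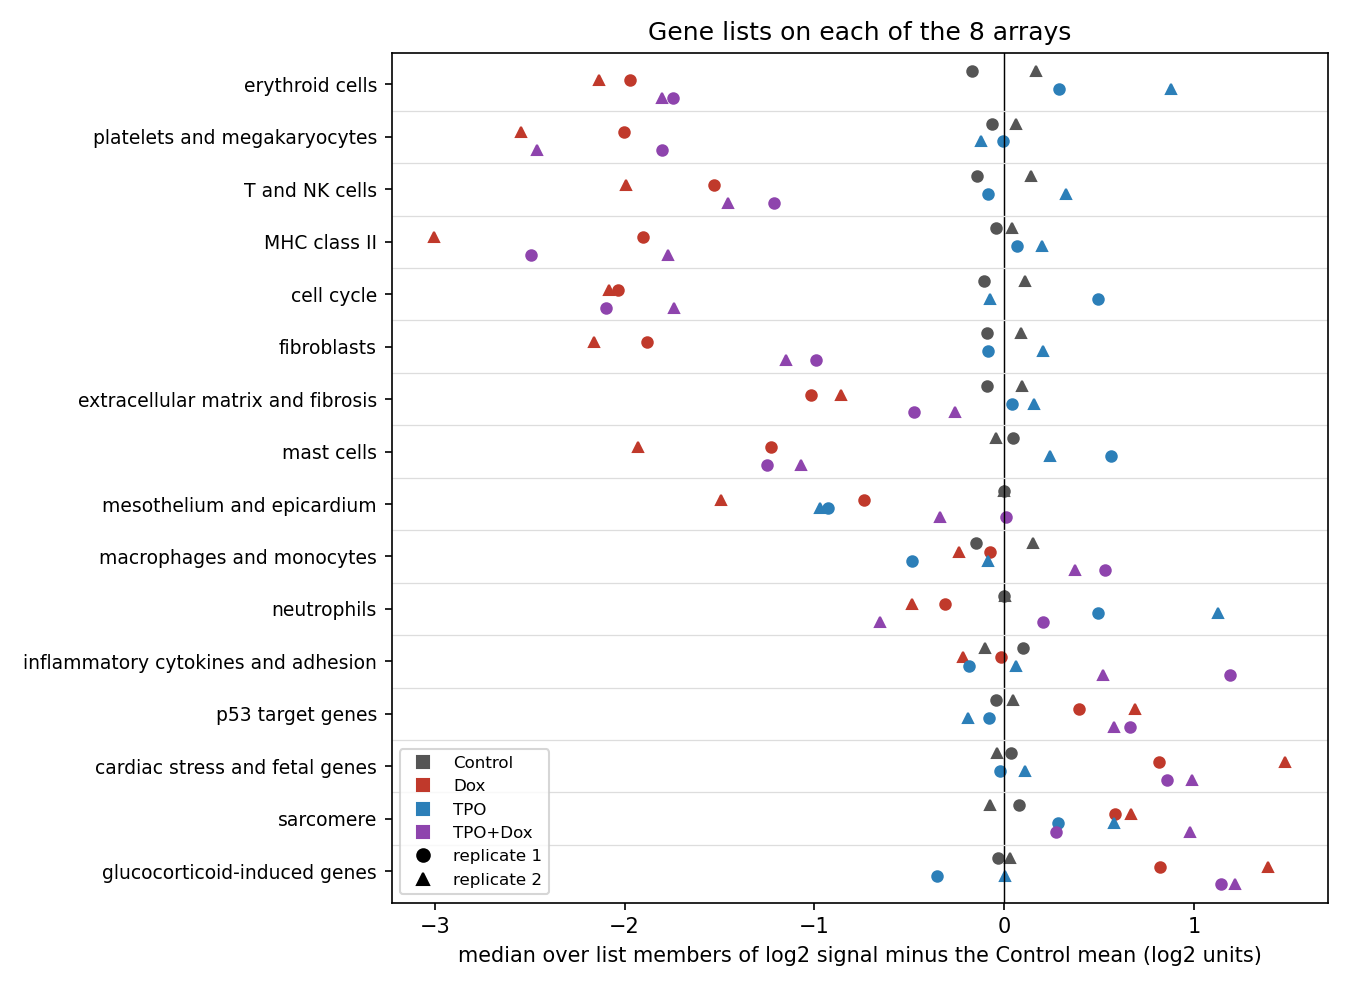
Median difference from the Control mean (log2) of 16 gene lists on each of the 8 arrays, coloured by group. The cell cycle median lies between -2.10 and -1.74 on all 4 Dox-treated arrays, and the inflammatory list stands at 1.19 and 0.52 on the TPO+Dox arrays only.

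TPO+Dox against Dox addressed what TPO changed in doxorubicin-treated hearts. No gene passed in limma (smallest adjusted p = 0.13), while 2981 had an unadjusted p under 0.05 against 1104.3 by chance. The smallest p belonged to C3, the central complement component, at 3.46 ± 0.38 higher with TPO, from 0.01 ± 0.48 (SD, n = 2) in Dox to 3.47 ± 0.49 in TPO+Dox (adjusted p = 0.13). P2ry6, a nucleotide receptor, was higher by 2.28 ± 0.27 and C10h16orf89 by at least 3.81-fold (adjusted p = 0.13 for each). Avil and Nxph1 (adjusted p = 0.13 for each) were well above background on neither Dox array and on 1 TPO+Dox array, so no fold is given.

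In camera at the preset correlation 14 lists passed, all higher with TPO, while 0 passed in fry (lowest adjusted p = 0.14). With normexp background correction 20 passed, 9 higher and 11 lower, and 6 of them were among the 14. Of 26 genes of inflammatory cytokines and adhesion, 24 were higher (median 1.26, adjusted p = 8.5e-11, and adjusted p = 0.52 with an estimated correlation); none passed over all genes and 8 did adjusted over the list alone. Values were 1.84 ± 0.36 for the interleukin 1 antagonist Il1rn, 3.74 ± 0.85 for the cytokine Il1b, 1.91 ± 0.50 for the adhesion molecule Vcam1 and 1.98 ± 0.32 for the bacterial lipoprotein receptor Tlr2. Of 34 matrix genes, 30 were higher (median 0.59, adjusted p = 5.5e-09, and adjusted p = 0.41 with an estimated correlation), 9 of them adjusted over the list alone. Col3a1 stood at 1.75 ± 0.27 and Bgn at 1.33 ± 0.30. Of 15 fibroblast markers, 14 were higher (median 0.87, adjusted p = 1.1e-08, and adjusted p = 0.41 with an estimated correlation), 6 adjusted over the list alone. Lum stood at 1.56 ± 0.33. These 3 calls held without each array in turn; with normexp background correction the matrix and fibroblast calls ended (adjusted p = 0.29 and 0.052).

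All 10 mesothelial markers were higher (median 0.83, adjusted p = 3.7e-05, and adjusted p = 0.52 with an estimated correlation), with Upk3b, a uroplakin of mesothelial cells, at 1.85 ± 0.61. Among 18 macrophage and monocyte markers, Adgre1, the F4/80 antigen, was at 3.43 ± 0.49 and passed adjusted over the list alone (list median 0.31, adjusted p = 0.0014, and adjusted p = 0.52 with an estimated correlation). Neutrophil markers had a median of 0.78 (adjusted p = 0.011, and adjusted p = 0.52 with an estimated correlation), with S100a8 at 1.95 ± 0.38 and Chi3l1 at 2.69 ± 0.63, both past the threshold adjusted over the list alone. Without TPO+Dox replicate 1 the calls of the mesothelial, macrophage, neutrophil and T and NK cell lists ended (adjusted p = 0.079, 0.079, 0.51 and 0.14). T and NK cell markers stood at a median of 0.63 (adjusted p = 0.0015) and fatty acid oxidation at 0.38 (adjusted p = 0.0014, and adjusted p = 0.59 with an estimated correlation for each), and both calls ended without Dox replicate 2 (adjusted p up to 0.19). Other lists that passed were the stress and unfolded protein response (0.22), cell cycle (0.11), glycolysis (0.16), iron handling (0.41), smooth muscle (0.17) and mast cells (0.81, medians in brackets), at adjusted p from 0.029 to 0.045. With an estimated correlation their adjusted p ran from 0.52 to 0.71, and each of these 6 ended without TPO+Dox replicate 1, at adjusted p up to 0.91. Of the 8 fits without 1 array, mast cells and smooth muscle passed in 1, glycolysis in 5 and the stress response and iron handling in 6. With lot as a block the calls of mast cells (adjusted p = 0.062), glycolysis (0.20) and smooth muscle (0.19) ended. With quantile normalization glycolysis, smooth muscle and iron handling (adjusted p = 0.079 for each) and the stress response (0.060) ended.

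Markers of red cells and platelets did not differ detectably between TPO+Dox and Dox (medians 0.32 and 0.15, adjusted p = 0.14 and 0.78), nor did p53 targets (-0.03, adjusted p = 0.63) or JAK-STAT and TPO receptor signalling (-0.04, adjusted p = 0.69). The other 22 lists also gave no call (adjusted p from 0.076 to 0.99). No overlap was seen for 39.7% of genes, against 33.3% by chance. Within lot 1, which left 1 TPO+Dox array, 20 genes passed, and with lot as a block 327; 327 also passed without TPO+Dox replicate 2 and 46 without TPO+Dox replicate 1.

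**Figure D2:**
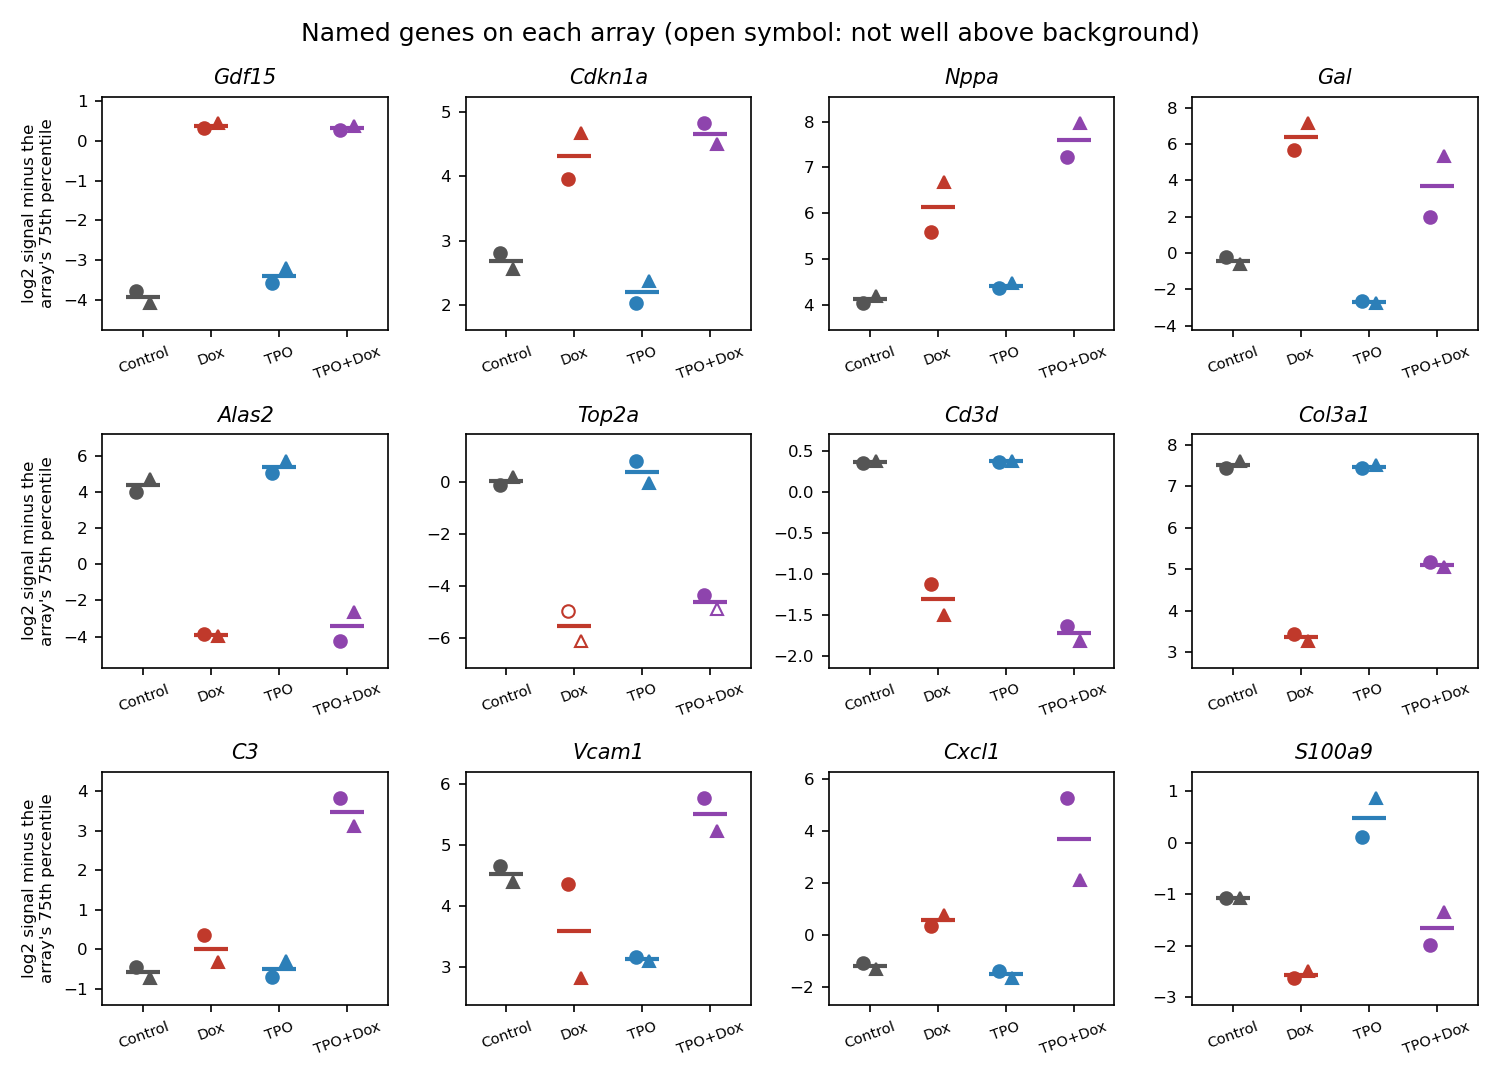
Log2 signal relative to the 75th percentile for 12 genes on each of the 8 arrays, with group means as bars and open symbols where the probe was not well above background. C3 stands at 3.81 and 3.12 on the TPO+Dox arrays and between -0.73 and 0.35 on the other arrays.

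TPO against Control addressed what TPO did to the heart alone. No gene passed in limma (smallest adjusted p = 0.11), while 3106 had an unadjusted p under 0.05 against 1104.3 by chance. The 5 smallest p were of Siae, Nol6, Or9s27, Pamr1 and Pcsk2, lower with TPO by at least 1.5-, 1.78-, 2.16-, 3.49- and 1.37-fold (adjusted p = 0.11 for each). All 5 probes were below background on both TPO arrays, whose lot had higher lowest detected signals than lot 1, and all 5 turned positive with normexp background correction.

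Neutrophil markers were higher with TPO as a list (median 0.80 over 10 genes, adjusted p = 0.0046, and adjusted p = 0.94 with an estimated correlation). Defa5, a defensin on that list, was at least 11.2-fold higher (adjusted p = 0.12 over all genes in limma). S100a9, the partner of S100a8, stood at 1.56 ± 0.36. Both were past the threshold adjusted over the list alone. Without Control replicate 1 the neutrophil call ended (adjusted p = 0.061). Neither this nor any other list passed in fry (0 lists, lowest adjusted p = 0.63). Mesothelial markers were lower (median -1.001 over 10 genes, adjusted p = 0.0036, and adjusted p = 0.94 with an estimated correlation), with Krt18, an epithelial keratin, at -1.50 ± 0.38, 1 gene past the threshold adjusted over the list alone. Erythroid markers (median 0.45, adjusted p = 0.054), platelet markers (0.02, adjusted p = 0.99) and JAK-STAT and TPO receptor signalling (0.04, adjusted p = 0.56) gave no call. The probe for Mpl, the TPO receptor, was well above background on 0 of 8 arrays. The other 35 lists gave no call either (adjusted p from 0.21 to 0.98). With normexp background correction 21 lists passed, 1 higher and 20 lower, and without Control replicate 2 8 passed, 7 higher and 1 lower.

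TPO against Control was confounded with the lot of the slides and with scan day, since no lot or scan day held arrays of both groups. With lot as a block, estimated from the TPO+Dox arrays alone, 23 genes passed, the neutrophil list kept its call (adjusted p = 9.5e-09) and the mesothelial list lost it (adjusted p = 0.68). The count was 543 without TPO+Dox replicate 1 or 2 and 0 without any other array. No overlap was seen for 58.4% of genes, against 33.3% by chance.

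TPO+Dox against TPO addressed what doxorubicin did in hearts also given TPO. It changed 768 genes, 269 higher and 499 lower, each without overlap between the arrays of the groups. The fitted change was at least 2-fold for each, though for 218 of them the fold is only a bound. Gal rose by 6.36 ± 0.98 (adjusted p = 0.019), Serpina3n by 5.96 ± 0.70 (adjusted p = 0.0092, well above background on 1 of 2 TPO arrays) and Gdf15 by 3.69 ± 0.29 (adjusted p = 0.0035). C3 rose by 3.96 ± 0.38 (adjusted p = 0.0050) and Cxcl1 by 5.18 ± 0.86 (adjusted p = 0.024). Cxcl2, a related neutrophil chemokine, rose by 3.70 ± 0.61 (adjusted p = 0.024) and Cxcl13, a B cell chemokine, by 3.88 ± 0.61 (adjusted p = 0.020). TPO+Dox replicates 1 and 2 stood far apart for Gal (1.98 and 5.35) and Cxcl1 (5.24 and 2.11). Vsig4, a complement receptor of macrophages, was at least 10.4-fold higher (adjusted p = 0.0044), Tmem63c at least 11.0-fold (adjusted p = 0.0066), Asb18 at least 5.47-fold (adjusted p = 0.011) and Foxq1 at least 5.06-fold (adjusted p = 0.037). Alas2 fell by 8.82 ± 0.54 (adjusted p = 0.0027), and the values were -9.98 ± 1.19 for Hbb (adjusted p = 0.0094) and -5.78 ± 0.98 for Slc4a1, the red cell anion exchanger (adjusted p = 0.025), each well above background on 1 of 2 TPO+Dox arrays. Alox15, a lipoxygenase, was at least 33.9-fold lower, Cd52 at least 82.8-fold and Ube2c, a ubiquitin enzyme of mitosis, at least 25.8-fold (adjusted p = 0.0027 for each).

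Of 44 cell cycle genes, 24 fell and 20 did not pass (29 adjusted over the list alone; median -2.33, adjusted p = 2.3e-17, and adjusted p = 0.24 with an estimated correlation). Falls passed for 8 of 15 erythroid markers, with 7 not passed (9 adjusted over the list alone; median -2.45, adjusted p = 1.7e-08, and adjusted p = 0.24 with an estimated correlation), and 4 of 9 platelet markers, with 5 not passed (6 adjusted over the list alone; median -1.22, adjusted p = 2.0e-06, and adjusted p = 0.23 with an estimated correlation). They also passed for 2 of 17 T and NK cell markers, with 15 not passed (13 adjusted over the list alone; median -1.39, adjusted p = 1.7e-08, and adjusted p = 0.24 with an estimated correlation), and 5 of 10 mast cell markers, with 5 not passed (6 adjusted over the list alone; median -1.62, adjusted p = 6.3e-05, and adjusted p = 0.24 with an estimated correlation). Fibroblast markers fell for 5 of 15, with 10 not passed (7 adjusted over the list alone; median -1.26, adjusted p = 0.00014, and adjusted p = 0.24 with an estimated correlation). Col3a1 fell by 2.37 ± 0.27 and Lum by 2.04 ± 0.33. MHC class II fell with 1 of 9 members passing (6 lower and 1 higher adjusted over the list alone, median -2.31, adjusted p = 0.0066, and adjusted p = 0.44 with an estimated correlation) and neutrophil markers with 2 of 10, Defa5 and S100a9 (7 lower and 2 higher adjusted over the list alone, median -1.21, adjusted p = 0.026, and adjusted p = 0.39 with an estimated correlation). Both calls ended without TPO+Dox replicate 2 (adjusted p = 0.074 and 0.45), and the neutrophil call also ended with normexp background correction (adjusted p = 0.12).

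Genes of inflammatory cytokines and adhesion rose with 6 of 26 members passing and 20 not (9 higher and 1 lower adjusted over the list alone; median 1.30, adjusted p = 1.7e-05, and adjusted p = 0.39 with an estimated correlation). Icam1, an adhesion molecule, rose by 2.77 ± 0.46 and Ccl20 by 3.29 ± 0.41 (well above background on 1 of 2 TPO arrays). Macrophage and monocyte markers rose for 4 of 18, with 14 not passed (7 higher and 2 lower adjusted over the list alone; median 0.47, adjusted p = 0.0030, and adjusted p = 0.24 with an estimated correlation). The scavenger receptor Cd163 rose by 2.64 ± 0.43 and the Fc receptor Fcgr2b by 2.92 ± 0.45. Glucocorticoid-induced genes rose for 4 of 19, with 15 not passed (9 adjusted over the list alone; median 1.17, adjusted p = 1.6e-07, and adjusted p = 0.24 with an estimated correlation). Fkbp5, a steroid receptor chaperone, stood at 2.74 ± 0.40. Cardiac stress genes had 2 of 17 higher, 1 lower and 14 not passed (5 higher and 1 lower adjusted over the list alone; median 1.09, adjusted p = 5.1e-06, and adjusted p = 0.30 with an estimated correlation). Nppa stood at 3.17 ± 0.43. Of 22 p53 targets, 3 rose, 1 fell and 18 did not pass (5 higher and 1 lower adjusted over the list alone; median 0.64, adjusted p = 4.7e-05, and adjusted p = 0.24 with an estimated correlation). Cdkn1a stood at 2.45 ± 0.34. Muscle atrophy and autophagy rose with 2 of 22 members passing, Bnip3 and Klf15 (5 adjusted over the list alone; median 0.58, adjusted p = 0.00060, and adjusted p = 0.24 with an estimated correlation). Mesothelial markers rose with none of 10 members passing (2 adjusted over the list alone; median 0.73, adjusted p = 0.0030, and adjusted p = 0.43 with an estimated correlation). Their call ended without TPO+Dox replicate 1 (adjusted p = 0.094).

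Fry kept 11 of the 15 list calls and ended those of inflammatory genes (adjusted p = 0.098), MHC class II (0.13), neutrophils (0.059) and mesothelium (0.16). The other 25 lists gave no call (adjusted p from 0.051 to 0.99), the matrix list among them (adjusted p = 0.051). Rises made up 35.0% of the calls and 52.6% when arrays were scaled by their median. Within lot 2, which left 1 TPO+Dox array, 2489 genes passed; with slide as a random block 38 passed (9 higher and 29 lower), with only the TPO+Dox and TPO arrays fitted 0, and with normexp background correction 3. The count was 26 without TPO replicate 1, 77 without TPO replicate 2, 448 without either Dox array and 3821 without TPO+Dox replicate 2. No overlap was seen for 50.1% of genes, against 33.3% by chance.

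TPO+Dox against Control addressed how far hearts given both agents stood from untreated ones. It changed 639 genes, 162 higher and 477 lower, each without overlap between the arrays of the groups. The fitted change was at least 2-fold for each, though for 264 of them the fold is only a bound. Cxcl1 rose by 4.87 ± 0.86 (adjusted p = 0.035), Serpina3n by 4.74 ± 0.70 (adjusted p = 0.022), Gdf15 by 4.23 ± 0.29 (adjusted p = 0.0039), C3 by 4.06 ± 0.38 (adjusted p = 0.0067) and Nppa by 3.47 ± 0.43 (adjusted p = 0.014). Vsig4 rose by 4.26 ± 0.48 (adjusted p = 0.010, well above background on 1 of 2 Control arrays), Bex1 by 4.13 ± 0.42 (adjusted p = 0.0077) and Hamp by 3.84 ± 0.77 (adjusted p = 0.048). Alas2 fell by 7.81 ± 0.54 (adjusted p = 0.0039), and the values were -7.65 ± 1.19 for Hbb (adjusted p = 0.025) and -5.00 ± 0.57 for Treml1 (adjusted p = 0.011), each well above background on 1 of 2 TPO+Dox arrays. Cd52 was at least 61.5-fold lower and Add2 at least 34.9-fold (adjusted p = 0.0039 for each), Clec1b, a platelet activation receptor, at least 9.18-fold (adjusted p = 0.0040) and Tent5c at least 16.8-fold (adjusted p = 0.013). Dnase1l3, a nuclease that digests extracellular DNA, fell by 5.16 ± 0.58 (adjusted p = 0.010) and was well above background on 1 of 2 TPO+Dox arrays.

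Cell cycle genes fell for 24 of 44, with 20 not passed (30 adjusted over the list alone; median -1.92, adjusted p = 4.2e-16, and adjusted p = 0.22 with an estimated correlation). Erythroid markers fell for 6 of 15, with 9 not passed (median -1.58, adjusted p = 7.5e-07, and adjusted p = 0.29 with an estimated correlation), platelet markers for 4 of 9, with 5 not passed (-1.82, adjusted p = 2.7e-07, and 0.18 as the adjusted p with an estimated correlation) and T and NK cell markers for 1 of 17, Cd3d, with 16 not passed (-1.48, adjusted p = 1.6e-07, and 0.31 as the adjusted p with an estimated correlation). Fibroblast markers fell for 3 of 15, with 12 not passed (median -1.21, adjusted p = 0.00062, and adjusted p = 0.31 with an estimated correlation), and mast cell markers (-1.29, adjusted p = 0.00062) and MHC class II (-2.13, adjusted p = 0.0069) fell as lists with no member passing (adjusted p = 0.29 and 0.48 with an estimated correlation). Adjusted over the list alone, the counts lower were 9 erythroid, 7 platelet, 12 T and NK cell, 7 fibroblast, 5 mast cell and 5 MHC class II genes.

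Rises passed for 2 of 17 cardiac stress genes (median 0.91, adjusted p = 1.2e-07, and adjusted p = 0.29 with an estimated correlation), 2 of 19 glucocorticoid-induced genes (1.01, adjusted p = 2.6e-07, and adjusted p = 0.28 with an estimated correlation), 4 of 26 inflammatory genes (1.00, adjusted p = 7.6e-06, and adjusted p = 0.35 with an estimated correlation) and 2 of 22 p53 targets (0.65, adjusted p = 1.7e-05, and adjusted p = 0.22 with an estimated correlation). Macrophage markers rose for 2 of 18, Cd163 and Fcgr2b (median 0.36, adjusted p = 0.031, and adjusted p = 0.35 with an estimated correlation), and atrial myocyte markers for 1 of 9, Nppa (0.62, adjusted p = 0.015, and adjusted p = 0.35 with an estimated correlation). Lists that rose with no member passing were sarcomere (median 0.45, adjusted p = 0.00021), muscle atrophy (0.51, adjusted p = 0.00068), circadian clock (1.16, adjusted p = 0.0015) and JAK-STAT and TPO receptor signalling (0.55, adjusted p = 0.026). With an estimated correlation their adjusted p was 0.44, 0.22, 0.22 and 0.31. Adjusted over the list alone, the counts higher were 8 cardiac stress, 8 glucocorticoid, 7 inflammatory, 6 p53, 3 macrophage, 7 circadian and 3 atrophy genes.

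The calls ended without TPO+Dox replicate 1 for the inflammatory list (adjusted p = 0.065), without Control replicate 1 or TPO+Dox replicate 1 for macrophages (up to 0.30), without Control replicate 1 or TPO+Dox replicate 2 for atrial myocytes (up to 0.13), and without Control replicate 1 or either TPO+Dox array for JAK-STAT (up to 0.12). With normexp background correction 14 lists passed, 2 higher and 12 lower, and 7 of them were among the 17. It ended the rises of cardiac stress (adjusted p = 0.12), glucocorticoid-induced genes (0.067), p53 targets (0.60), sarcomere (0.50), muscle atrophy (0.63), circadian clock (0.076), JAK-STAT (0.82), macrophages (0.77) and atrial myocytes (0.12), and the fall of mast cells (0.36). Fry kept 10 of the 17 list calls and ended those of inflammatory genes (adjusted p = 0.15), sarcomere (0.20), MHC class II (0.13), muscle atrophy (0.072), JAK-STAT (0.26), macrophages (0.14) and atrial myocytes (0.13). The other 23 lists gave no call (adjusted p from 0.062 to 0.97). Rises made up 25.4% of the calls, 46.8% with scaling by the median, 36.7% with quantile normalization and 41.2% among genes well above background on all 8 arrays. Within lot 1, 263 genes passed, with slide as a random block 91, with only the TPO+Dox and Control arrays fitted 0, and with normexp background correction 3. The count was 0 without either Control array, 159 without either TPO array, 243 without either Dox array and 2307 without TPO+Dox replicate 1. No overlap was seen for 44.2% of genes, against 33.3% by chance.

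Gdf15 rose, Alas2 fell and the cell cycle list was lower in all 3 comparisons of a Dox-treated with a Dox-free group. Dox against Control and TPO+Dox against TPO share no array. In both, 132 genes rose and 292 fell, where independent calls would give 4.13 and 16.3. None was called in opposite directions. Both sets of calls used the same variance per gene and are not fully independent, so the numbers for independent calls may be too low. Of the 1062 genes changed by Dox, 1015 (95.6%) had the same sign under TPO. Across all genes the fold changes correlated at r = 0.55 with a slope of 0.58, and at r = 0.886 over the genes changed by Dox. TPO+Dox against Control was left out of this count because it shares the Control arrays with Dox against Control. Lots split these comparisons. With lot as a block r was 0.67 and the slope 0.68, the same values as without TPO+Dox replicate 1. Only TPO+Dox spanned both lots, so the lot block is not a separate check here. Without TPO+Dox replicate 2 r was 0.35 and without Control replicate 1 it was 0.42 with a slope of 0.40. The slope was 0.38 with normexp background correction.

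The matrix and fibroblast lists stood closer to Control in TPO+Dox than in Dox. The single gene Cd3d stood further from it, unlike its own T and NK cell list. Medians of that list from the Control mean were -1.529 and -1.995 in Dox and -1.213 and -1.455 in TPO+Dox. The question of whether TPO turned the Dox response back was tested over all genes. The fold changes of TPO+Dox against Dox and of Dox against Control correlated across genes at r = -0.46, and 85.4% of the 1062 genes changed by Dox had a TPO+Dox mean on the Control side of the Dox mean. Both comparisons use the same Dox arrays, which by itself pushes r below 0. In 100 simulations in which TPO+Dox equalled Dox, r was -0.20 on average (-0.71 to 0.43) and the share 60.5% (21.3 to 90.0%). The simulated share was over 3145.9 called genes on average rather than 1062, so the shares cover unlike gene sets. The covariance was -0.29 as observed and -0.12 as simulated (-0.75 to 0.18). The observed values lay within the simulated ranges. These are wide, since all simulated noise was mixed from the observed replicate differences and genes moved together. The simulations could thus hardly exclude either outcome. Without TPO+Dox replicate 1 r was -0.26 and the share, over the genes called in that fit, 73.4%. With normexp background correction r was -0.19. With 2 Dox arrays, no split gives each comparison its own pair, so part of the excess over the simulated mean may come from the shared arrays. Cd3d stood at 0.36 and 0.38 in Control, -1.12 and -1.50 in Dox and -1.63 and -1.81 in TPO+Dox. Col3a1 stood at 7.43 and 7.61 in Control, 3.43 and 3.28 in Dox and 5.17 and 5.04 in TPO+Dox, and Alas2 at 4.03 and 4.71, -3.85 and -3.96, and -4.22 and -2.65.

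The interaction of Dox and TPO addressed whether the effect of TPO differed between hearts with and without doxorubicin. No gene passed in limma (smallest adjusted p = 0.67), while 1441 had an unadjusted p under 0.05 against 1104.3 by chance; the exception among 8 fits without 1 array was without TPO+Dox replicate 2, with 897. The smallest p were of Pamr1, P4ha3, C3, Adgre1 and Slc13a3 (adjusted p = 0.67 for each). Pamr1 was not well above background on any array outside Control. The collagen-modifying enzyme P4ha3 stood at 2.64 ± 0.38, C3 at 3.36 ± 0.54 and Adgre1 at 4.18 ± 0.69. Slc13a3, a transporter, stood at 4.27 ± 0.72 and was well above background on 1 of 2 TPO arrays. In camera 10 lists passed, 9 of them positive, and 0 in fry (lowest adjusted p = 0.25), with adjusted p from 0.39 to 0.98 with an estimated correlation. Mesothelial markers had an interaction of 1.79 (adjusted p = 7.7e-10; 10 of 10 positive), inflammatory genes 1.38 (adjusted p = 7.7e-10; 25 of 26), fibroblast markers 0.88 (adjusted p = 1.1e-05; 14 of 15), macrophage markers 0.71 (adjusted p = 0.00010; 16 of 18) and matrix genes 0.34 (adjusted p = 0.00015; 25 of 34). Adjusted over the list alone, 8, 1, 1, 1 and 0 members passed. The inflammatory median was 2.07 with TPO+Dox replicate 1 alone and 0.68 with replicate 2 alone. Vcam1 stood at 3.30 ± 0.70 and Krt18 at 2.41 ± 0.54. Sarcomere genes had a negative interaction of -0.60 (adjusted p = 0.013; 20 of 20 negative), which ended without TPO+Dox replicate 1 (adjusted p = 0.19). Apoptosis regulators, fatty acid oxidation, the interferon response and the stress and unfolded protein response had interactions of 0.37, 0.38, 0.53 and 0.32 (adjusted p = 0.013, 0.039, 0.041 and 0.042). The other 30 lists gave no call (adjusted p from 0.052 to 0.98).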

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

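The tests of slide, lot, blood content, array label and cell composition below were chosen after the results were seen; the test of probes near the background was chosen before the data were examined. Lists whose effect of TPO differed between hearts with and without Dox had median interactions of 1.377 for inflammatory cytokines and adhesion, 1.787 for mesothelium and epicardium, 0.8836 for fibroblasts, 0.7131 for macrophages and monocytes and 0.3378 for matrix and fibrosis. They were weighed together below.

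Markers of red cells, platelets and T and NK cells and genes of cell division were lower in both Dox groups, against Control and against TPO. Within slide 2, and so 1 lot and scan day, the list medians of Dox against 1 Control array stayed lower, the highest at -2.055. Within lot 2, scanned on 1 day, those of 1 TPO+Dox array against TPO stayed lower, the highest at -1.281. Lot and scan day were thus excluded as candidate explanations, and slide was for Dox against Control. The TPO+Dox and TPO arrays of lot 2 lay on different slides, so slide stays open for that comparison. Less blood in the sampled hearts might lower blood cell markers alike, yet neutrophil markers stood above erythroid ones by 1.614 in Dox against Control and 1.243 in TPO+Dox against TPO. Permutation tests that shuffled genes between the neutrophil and erythroid lists gave p = 0.0647 and 0.25. They treat genes as independent and do not measure the spread between hearts, so less blood stays open. Cell counts in blood or marrow of the same rats would separate fewer cells from less blood.

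The TPO+Dox arrays differed more between replicates than those of any other group. The array lot, which went with scan day, could be a part. The difference of replicate 2 from replicate 1 correlated across genes with that of TPO from Control at r = 0.5837. Over 16540 genes well above background on all 8 arrays r was 0.666. TPO against Control was itself confounded with lot and scan day. This r therefore cannot tell the lot from a response to TPO that differed between the replicates. Probes near the background were excluded, since the SD stayed at 0.919 over those genes and was at most 0.617 in the other groups. An array without Dox under a TPO+Dox label was excluded, since the Dox response had slopes of 0.7303 and 0.749 on the TPO+Dox arrays and 0.018 and -0.003 on the TPO arrays. An exchange between a TPO+Dox and a Dox array was not tested, and arrays of 1 lot would test the part of the lot.

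The inflammatory, mesothelial, fibroblast, macrophage and matrix lists were higher with TPO under Dox beyond the effect of TPO alone. The array lot could enter, since only 1 TPO+Dox array shared the lot of the TPO arrays, but with TPO+Dox replicate 2 alone, where the lot cancels, 5 of 5 lists passed the same way at the preset correlation, with medians of 0.68, 1.65, 0.76, 0.78 and 0.42 for inflammatory, mesothelial, fibroblast, macrophage and matrix. A lower share of heart muscle cells could raise all other cell types, and the 100 genes of these lists stood 0.884 above the 31 genes of endothelium and smooth muscle (medians 0.956 and 0.072). On single arrays that difference had an interaction of 0.748 with a standard error of 0.358 between replicates. The sarcomere list had an interaction of -0.5958 with 20 of 20 members negative (camera adjusted p = 0.013, and 0.95 with an estimated correlation). Yet its medians against Control were 0.27 and 0.98 in TPO+Dox, 0.58 and 0.67 in Dox, and 0.28 and 0.58 in TPO. That interaction thus does not tell whether TPO+Dox samples held fewer muscle cells, and a lower share stays open. Counts of cells in heart sections would test it directly.

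The sarcomere call ended without TPO+Dox replicate 1. Apoptosis regulators stood at 0.3664 and ended without Control replicate 2 or TPO+Dox replicate 1. Fatty acid oxidation stood at 0.3754, the interferon response at 0.5256 and the stress and unfolded protein response at 0.3176, and each ended in at least 4 of the 8 fits without 1 array.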

How the results depend on the processing

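The fits within slide 2, lot 1 and lot 2 and the lists with a lot block or without 1 array were chosen after the results were seen. Counts are of genes past the threshold (higher and lower in brackets), and for all shifts the cause was not tested. With normexp background correction Dox against Control, TPO+Dox against TPO and TPO+Dox against Control each had 3 (0 and 3). Its correlation of the reversal was -0.19, the share toward Control 100% of only 3 genes, and the slope of the Dox response 0.38. The lists passed were 20 (9 and 11) for TPO+Dox against Dox and 21 (1 and 20) for TPO against Control. They were 14 (2 and 12) for TPO+Dox against Control and 19 (17 and 2) for the interaction. It moved the median of all genes by 0.10, 0.37, 0.40 and 0.45 for Dox against Control, TPO+Dox against Dox, TPO against Control and TPO+Dox against Control. Genes whose direction it turned were Nol6 (0.58), Or9s27 (0.51), Pamr1 (0.39), Pcsk2 (0.76) and Siae (0.77) for TPO against Control, and Aldh1l2 (0.66), Epb42 (0.17), Nfe2 (0.23), Phox2b (0.78) and Scgb1a1 (1.02) for TPO+Dox against Control.

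With no filter the counts were 483 (142 and 341) for Dox against Control, 319 (102 and 217) for TPO+Dox against TPO and 178 (58 and 120) for TPO+Dox against Control, with a slope of 0.48; medians moved by 0.14, 0.23, -0.14, 0.19 and -0.18 from TPO+Dox against Dox on. With the filter on all 8 arrays TPO+Dox against TPO had 409 (176 and 233) and TPO+Dox against Control 194 (80 and 114). Quantile normalization gave TPO against Control 1 (1 and 0) and TPO+Dox against Control 412 (151 and 261). Median scaling moved the median by 0.25 for TPO+Dox against Dox and against TPO, 0.26 against Control and 0.24 for the interaction. With only the groups compared, TPO+Dox against TPO and TPO+Dox against Control had 0.

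The labels do not say whether replicate numbers pair the arrays. Replicate differences of the groups correlated across genes at -0.25 to 0.25. Some of these differences also carry slide and lot, so they cannot tell whether arrays were paired. The replicate block gave 691 (210 and 481) for Dox against Control, 344 (113 and 231) for TPO+Dox against TPO and 188 (50 and 138) for TPO+Dox against Control. It ended the mast cell list call of TPO+Dox against Dox (adjusted p = 0.087). The slide block (correlation within slides 0.571) gave 2102 (857 and 1245), 38 (9 and 29) and 91 (26 and 65), with a slope of 0.49. Only TPO+Dox spanned both lots, so a lot block uses up the difference between its arrays. Except for TPO against Control, it therefore repeats a fit without 1 TPO+Dox array and is not a separate check. The lot block gave 2133 (862 and 1271) for Dox against Control, 327 (94 and 233) for TPO+Dox against Dox and 23 (16 and 7) for TPO against Control, a response correlation of 0.67 and slope of 0.68, and 4 lists for TPO against Control and 6 for the interaction; it moved the median of TPO against Control by -0.14. The scan day block and the fit within slide 2 gave Dox against Control 508 (230 and 278), and the scan day block and the fit within lot 2 gave TPO+Dox against TPO 2489 (866 and 1623). Within lot 1, TPO+Dox against Dox had 20 (19 and 1) and TPO+Dox against Control 263 (86 and 177).

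With an estimated correlation 0 lists passed in each comparison. With fry, 0 passed for TPO+Dox against Dox, TPO against Control and the interaction, and 10 (4 and 6) for TPO+Dox against Control. Without 1 array at a time, where a lone array is assumed to vary like the other groups, counts were 48 (without Dox replicate 2) to 2133 (without either TPO+Dox array) for Dox against Control, 0 to 327 (without TPO+Dox replicate 2) for TPO+Dox against Dox, 0 to 543 (without either TPO+Dox array) for TPO against Control, 26 (without TPO replicate 1) to 3821 (without TPO+Dox replicate 2) for TPO+Dox against TPO, 0 (without either Control array) to 2307 (without TPO+Dox replicate 1) for TPO+Dox against Control, and 0 to 897 (without TPO+Dox replicate 2) for the interaction. Lists ran 15 to 22, 4 (without TPO+Dox replicate 1) to 16, 1 (without Control replicate 1) to 8 (without Control replicate 2), 15 to 19, 14 to 19 and 6 (without Control replicate 2 or TPO+Dox replicate 1) to 14. The reversal correlation ran from -0.57 to -0.26 (without TPO+Dox replicate 1). The share toward Control ran from 73.4 to 94.6%, over the genes called in each fit. The response correlation ran from 0.35 (without TPO+Dox replicate 2) to 0.67, and the slope from 0.40 to 0.68.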

Other observations

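Some genes changed after Dox in lists that gave no call. Aplnr and Apln, the apelin receptor and its ligand, which act on vessels and heart contraction, fell, with values of -2.91 ± 0.47 (adjusted p = 0.018) and -3.31 ± 0.73 (adjusted p = 0.046), and Fgf2, a growth factor of vessels, rose by 1.46 ± 0.32 (adjusted p = 0.047). Tfrc, the transferrin receptor that takes up iron, was at -2.89 ± 0.49 (adjusted p = 0.022). Of the genes of drug transport, Abcb1b, a drug efflux pump, was at least 6.07-fold higher (adjusted p = 0.023), Abcb4 rose by 1.91 ± 0.36 (adjusted p = 0.030) and Abcc2 fell by 1.98 ± 0.29 (adjusted p = 0.015).

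Phgdh, an enzyme of serine synthesis, was at -1.53 ± 0.30 after Dox (adjusted p = 0.031) and Aldh18a1, of proline synthesis, at -1.90 ± 0.30 (adjusted p = 0.017), within a stress response list that gave no call (adjusted p = 0.53). Gap43, a growth protein of nerve endings, fell by 2.48 ± 0.29 (adjusted p = 0.0071). Mcl1, which blocks apoptosis, rose by 1.62 ± 0.33 (adjusted p = 0.037), and Faslg, the death ligand of killer cells, was at -2.22 ± 0.41, well above background on 1 of 2 Dox arrays. Cd163, a scavenger receptor of macrophages, rose by 2.39 ± 0.43 (adjusted p = 0.025) while Adgre1 fell by 2.61 ± 0.49 (adjusted p = 0.029).

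In these limma results some lists had a median and a test of opposite sign without a call in Dox against Control: endothelial cells (median 0.05, mean -0.15), angiogenesis (0.04, -0.23) and drug transport (0.16, -0.21) were tested as lower. TPO+Dox replicate 2 correlated with the TPO arrays at 0.955 to 0.958 across genes and replicate 1 at 0.921 to 0.924. The first 3 principal components held 42.8, 23.5 and 14.8% of the variance. Hearts of more rats per group, spread over slides and lots, would be needed to test the effect of TPO by gene.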
